A study of Homo sapiens with 6 samples.

How the data were processed

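RNA from 3 control and 3 PM2.5-treated samples of the human endothelial line EA.hy926 was sequenced as 150 bp paired-end reads, per the labels' protocols. The submitters' processing notes name fastp, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3, DESeq2 1.20.0, edgeR 3.22.5, GATK 4.1.1.0 and the build hg19, with no role or order. The strandedness of the library and of the counting, the dose and the duration of the treatment are not given in the sources used here.

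The authors deposited a single table with 1 column per sample, whose header names no unit. Its values were read as FPKM: value times gene length was a whole multiple of a fixed step in each column (100% of values whole within 0.01 read), and the columns summed to 266705 to 409926. The steps gave whole reads per gene and an effective library size per column, which equalled the median-of-ratios size factor of the recovered reads times the geometric mean of the read totals in all 6 libraries. The deposited FPKM are therefore scaled by these size factors (0.879 to 1.20), which include depth. The effective library size was 0.925 to 1.08 times the reads in genes, and this is the scaling beyond depth. The table has 59304 rows, of which 58735 carry Ensembl identifiers and 569 are unannotated loci assembled by the authors; 298 of the latter passed the filter on low values. Although the notes name hg19, the coordinates of 58690 rows (99.9% of the Ensembl identifiers) are those of GENCODE 29 on GRCh38, so positions are given on GRCh38 as the table has them.

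Reads in genes numbered 14805687 to 18233611 per library, so depth itself limits only genes with few reads. PM2.5 replicates 1 and 2 had few genes with 1 read (182 and 276, against 1899 to 2269 in the other 4 libraries). The duplicate check on replicate pairs gave a chi-square per degree of freedom of 4.1 to 205.2 across genes, so all replicate pairs differed by more than sampling noise. The SD of a library's log2 values about its group mean, across genes, was 0.116 to 0.140 in controls and 0.613, 0.414 and 0.321 in PM2.5 replicates 1, 2 and 3.

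The test planned for counts was not used because the values are FPKM, and the test fixed for that case was run instead: limma 3.58.1 (R 4.3.3) with an intensity trend on log2(FPKM + 1), over genes with a mean of at least 1 FPKM, PM2.5 against control with the group as the only term. P-values were adjusted by Benjamini-Hochberg over all 11495 genes tested, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes near or under 1 FPKM. An exact permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1, so single genes were tested in the limma fit across genes. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

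The test was checked on simulated data for this comparison. The simulation set only the spread of the libraries. That spread was taken about a group mean that includes the library itself, so it may be understated. The loss of genes with few reads and the relation to gene length seen in some treated libraries were not simulated. The recovery and false-call figures therefore hold for the simulated spread and may not hold for these libraries. With the spread of the controls in both groups and 11301 genes tested, 96.9% of genes changed 2-fold and 100% of those changed 4-fold were recovered, with 16 false calls among 206. With each library given its own spread and 11319 genes tested, 20% of genes changed 2-fold, 85.9% of those changed 4-fold and 100% of those changed 8-fold were recovered, with 6 false calls among 135.

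Before the data were examined, 28 gene lists were fixed from textbook knowledge of particle toxicology, endothelial biology and other cell types, and 26 of them had the 3 tested members needed for a list test. Of the 488 tested genes in these lists, 16 belong to more than 1 list. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists; 4 calls (NRF2 targets, integrated stress response, heat shock proteins, endothelial identity) also held with an estimated correlation. The genes named in the results were chosen by a rule fixed at the same time. It takes the 10 largest increases and the 10 largest decreases among called protein-coding genes with a mean of at least 5 CPM and no overlap between groups, a fixed set of genes of interest, the 4 members with the smallest p of each called list and up to 2 of each other list, 108 genes in all, of which some are not reported here. Other genes are said to have been named after their values were seen.

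Alternatives fixed in advance were other scalings, filters and pseudocounts, limma-voom on recovered reads, a block for the replicate number, protein-coding nuclear genes only, a minimum fold change, an estimated correlation, fry for the lists, and leaving out each library in turn. Leaving out PM2.5 replicates 1 and 2 together was added after the data were seen. The planned count models were not run, since the plan set the limma test for deposited values that are not counts.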

Results

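The series holds 6 bulk RNA-seq libraries of EA.hy926 cells, an immortalised human line made by fusing umbilical vein endothelial cells with A549 lung carcinoma cells. Per the labels, 3 libraries come from control cells and 3 from cells treated with PM2.5, the fine fraction of airborne particulate matter. The dose and the duration of the treatment are not given in the labels. The deposited table gives FPKM per gene, from which whole reads could be recovered. The control libraries held 18233611, 14984090 and 15228591 reads in genes, and the PM2.5 libraries 15156999, 17671899 and 14805687. Genes with at least 1 read numbered 21524, 20728 and 20685 in the controls, against 13752, 17053 and 20292 in PM2.5 replicates 1, 2 and 3. The PM2.5 libraries also differed more from each other (Pearson's r across genes of the log2 values, 0.856 to 0.970) than the controls did (0.989 to 0.992). Mitochondrial ribosomal RNA took 1.06, 0.741 and 0.696% of the reads in PM2.5 replicates 1, 2 and 3, against 0.343 to 0.436% in the controls. Nothing in the labels says that the replicates are separate cultures, so the p-values measure the spread between these libraries, which may be technical.

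**Figure D1:**
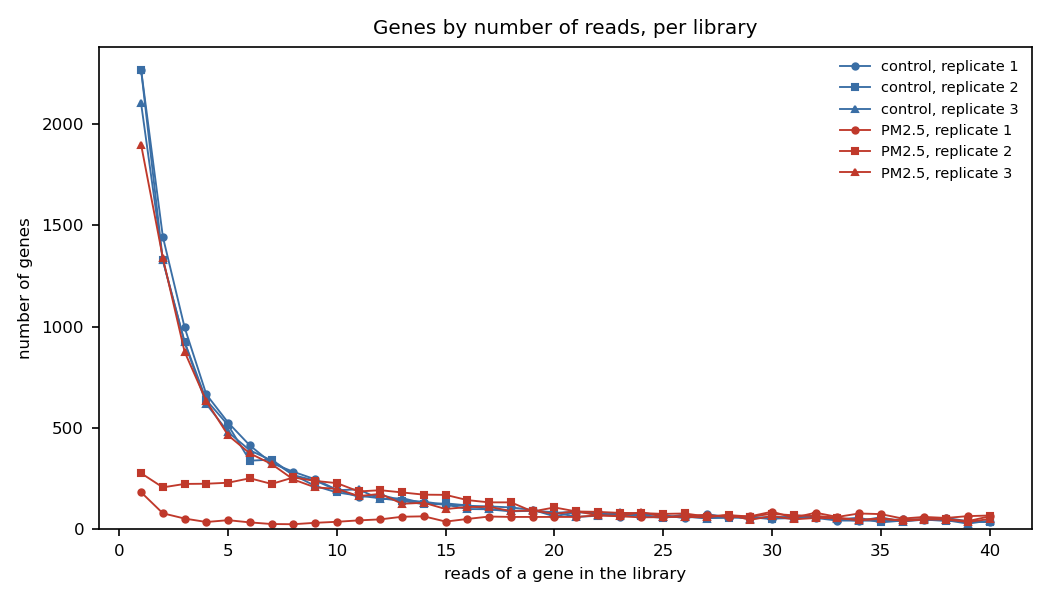
Number of genes (vertical axis) by the reads of a gene in a library, from 1 to 40 (horizontal axis), with 1 line per library (blue control, red PM2.5, marker by replicate). PM2.5 replicates 1 and 2 hold 182 and 276 genes with 1 read, and the other 4 libraries 1899 to 2269.

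The single comparison, PM2.5 against control, addresses the series' stated aim of studying how PM2.5 acts on cells that model the cardiovascular system. Inflammatory, antioxidant and heat shock genes rose in the PM2.5 libraries, while genes of endothelial identity and of cell division fell. By count, 15 of 25 inflammatory, 8 of 27 antioxidant and 9 of 19 heat shock genes were called higher, and 12 of 20 endothelial identity and 16 of 31 cell cycle genes lower; the inflammatory and cell cycle lists passed camera at the preset correlation only (each adjusted p = 0.0708 with an estimated correlation). CXCL8, the chemokine interleukin-8, had the largest log2 fold change of the genes named by the fixed rule, from 8.09 ± 1.65 FPKM in controls to 468 ± 150 FPKM in PM2.5 (SD, n = 3 each; log2 fold change 5.66, SE 0.27, limma adjusted p = 7.33e-04). HMOX1, the heme-degrading enzyme heme oxygenase 1, went from 15.4 ± 0.632 to 256 ± 23.8 FPKM (log2 fold change 3.97, SE 0.14, adjusted p = 4.26e-04). MMP1, interstitial collagenase, was already abundant at 686 ± 82.0 FPKM and reached 7994 ± 696 FPKM (3.54, SE 0.18, adjusted p = 7.33e-04). In the other direction, MMRN2, an endothelial matrix glycoprotein, dropped from 157 ± 16.4 to 13.4 ± 4.56 FPKM (-3.50, SE 0.26, adjusted p = 0.00310). EDN1, the precursor of the vasoconstrictor endothelin 1, went from 25.6 ± 2.88 to 2.66 ± 0.330 FPKM (-2.86, SE 0.14, adjusted p = 7.33e-04).

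The other genes with the largest increases were MMP10 (4.38), CXCL2 (4.03), the inducible heat shock protein HSPA6 (3.97), the activin subunit INHBA (3.51), the chemokine CCL3 (3.21), the proton pump subunit ATP6V0D2 (3.13) and the anti-apoptotic BCL2A1 (3.09). The other large decreases were in the somatostatin receptor SSTR5 (-3.08), the BMP target ID1 (-3.04), P-selectin (SELP, -2.80), the diaphragm protein PLVAP (-2.49), the Notch-modifying enzyme LFNG (-2.48), the hedgehog inhibitor HHIP (-2.33), COL9A3 (-2.31) and the scavenger receptor STAB1 (-2.28). SSTR5 and LFNG were listed at 0 in PM2.5 replicate 1. On GRCh38, CXCL8 (ENSG00000169429) lies on chromosome 4 at 73740506 to 73743716 and HMOX1 (ENSG00000100292) on chromosome 22 at 35380361 to 35394214. MMP1 (ENSG00000196611) lies on chromosome 11 at 102789920 to 102798160, MMRN2 (ENSG00000173269) on chromosome 10 at 86935540 to 86969481, and EDN1 (ENSG00000078401) on chromosome 6 at 12290363 to 12297194.

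**Figure D2:**
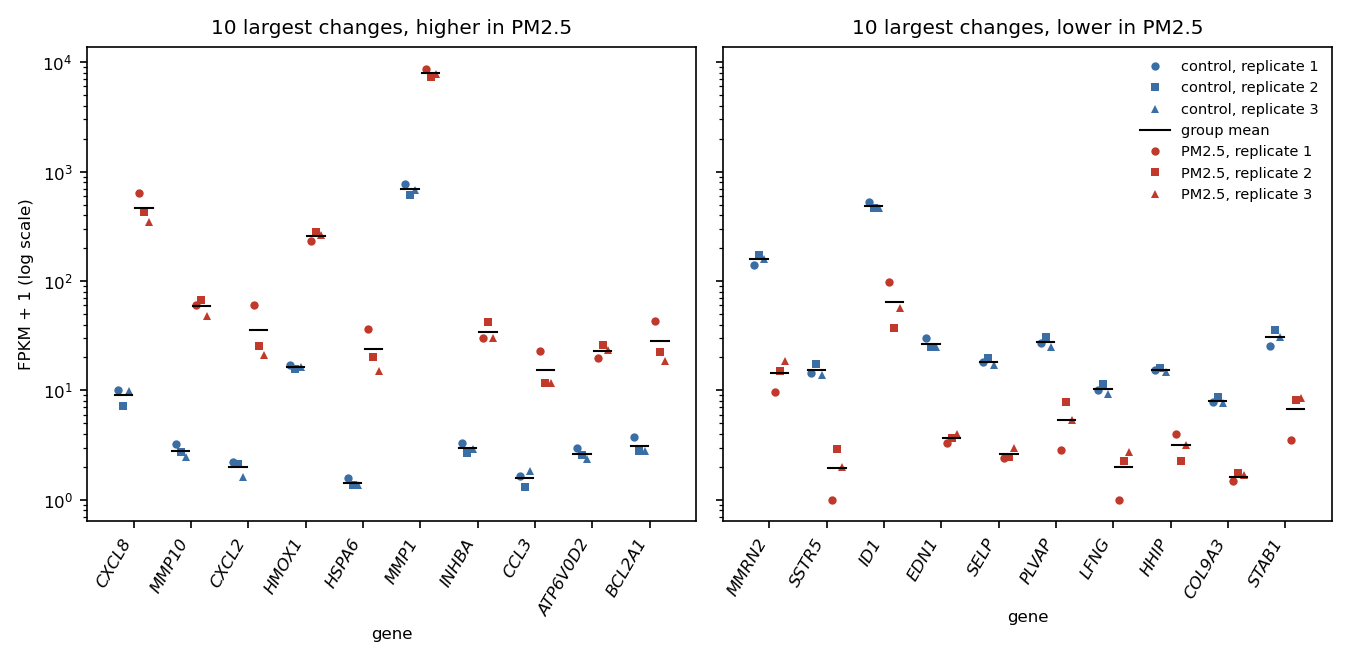
FPKM + 1 (log axis) of the 10 genes with the largest increase (left) and the 10 with the largest decrease (right) that the fixed rule names, with 1 point per library (blue control, red PM2.5, marker by replicate) and a black line at the mean of FPKM + 1 of each group. The rule admits only genes whose groups do not overlap; CXCL8 lies at 6.19 to 9.15 FPKM in the controls and at 343 to 635 FPKM in PM2.5.

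In all, 261 genes were higher and 319 lower in PM2.5 among 11495 tested (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p under 0.05), with 161 and 187 of these changed at least 2-fold on that scale. The values of the 2 groups did not overlap for 36.2% of the tested genes, where chance gives 10%. These counts depend on single libraries. Without control replicate 1, 2 or 3 they were 34, 17 and 20 higher and 34, 8 and 12 lower. Without PM2.5 replicate 1, 2 or 3 they were 1078, 106 and 153 higher and 1390, 132 and 185 lower. Without PM2.5 replicates 1 and 2 together, a setting chosen after seeing the data, 914 were higher and 1083 lower.

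Inflammatory cytokine and NF-kB target genes rose as a group: 15 of 25 tested members were higher and 1 lower (18 and 1 adjusted over the list alone). Their median log2 fold change was 1.43, with a camera adjusted p of 4.44e-15 (adjusted p = 0.0708 with an estimated correlation). In PM2.5 replicates 1, 2 and 3 taken singly the median of the list was 1.80, 1.42 and 0.92. Beside CXCL8, they included the neutrophil attractant CXCL3 (2.98, adjusted p = 0.00137), the alarmin IL1A (2.37, adjusted p = 0.00251), LIF (2.60, adjusted p = 0.00375) and IL6 (2.69, adjusted p = 0.0112). The cytokine IL6 went from 3.07 ± 1.10 to 26.1 ± 11.6 FPKM (SD, n = 3). The member that fell was TNFAIP2 (-0.83), named after its value was seen. CCL2, which encodes the monocyte attractant MCP-1, stood at 12.4 ± 1.40 FPKM in controls and 19.2 ± 10.1 FPKM in PM2.5 and did not pass the test (adjusted p = 0.425). It read 30.9, 12.7 and 14.0 FPKM in PM2.5 replicates 1 to 3, so its higher mean rests mainly on replicate 1. Of 20 tested immediate early genes, which are switched on within minutes of many stimuli, 9 rose and 0 fell (10 and 1 adjusted over the list alone). Without PM2.5 replicate 1, 13 of them were higher and 3 lower. Camera gave these early genes an adjusted p of 2.83e-05 (adjusted p = 0.0947 with an estimated correlation). EGR1 (2.32), SPRY2 (1.71), ATF3 (1.65) and DUSP5 (1.09) had the smallest p-values among them.

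Antioxidant targets of NRF2 rose: 8 of 27 were higher and 0 lower (19 and 1 adjusted over the list alone). The list had a median of 0.72 and a camera adjusted p of 2.15e-11. GCLM, the regulatory subunit of the enzyme that limits glutathione synthesis, went from 8.67 to 26.5 FPKM (1.502, adjusted p = 0.00496). TRIM16L (1.31, adjusted p = 0.00619) and the ferritin heavy chain FTH1 (1.19, adjusted p = 0.0125) also rose. NQO1, a widely used NRF2 target, stood at 137 ± 3.92 and 179 ± 59.4 FPKM (adjusted p = 0.482). Its log2 fold change was 0.33, and 0.09 without PM2.5 replicate 1. Targets of the integrated stress response and ATF4 rose in 10 of 23 members and fell in 0 (15 and 0 adjusted over the list alone; camera adjusted p = 7.68e-12). Among them were CEBPB (1.69), ATF3 (1.65), PPP1R15A (1.49) and TRIB3 (1.06). The transcription factor DDIT3, also called CHOP, rose as well (2.09, SE 0.35, adjusted p = 0.0260). For heat shock proteins, 9 of 19 rose and 0 fell (14 and 1 adjusted over the list alone; camera adjusted p = 8.11e-10). HSPA6 (3.97), HSPA1B (2.09), HSPA1A (1.89) and DNAJB1 (0.98) had the smallest p-values among them. The call of these 3 lists held with an estimated correlation (adjusted p = 0.0391, 0.0369 and 0.0391). Without PM2.5 replicate 1, the members higher numbered 19, 18 and 15.

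ER chaperones and unfolded protein response genes did not pass the list test (2 of 19 higher and 1 lower, 2 and 3 adjusted over the list alone; camera adjusted p = 0.414). DNAJB9, an ER co-chaperone, and the transcription factor XBP1 rose by 1.06 and 0.81, and the disulfide isomerase PDIA4 fell by 0.85, on the log2 scale; XBP1 was named after its value was seen. Without PM2.5 replicate 1, 4 members were higher and 7 lower. No metallothionein or zinc exporter passed the limma test (0 of 4, and 0 adjusted over the list alone; 1 at an unadjusted p under 0.05; camera adjusted p = 0.373). MT2A read 3292, 1121 and 1304 FPKM in PM2.5 replicates 1 to 3 against 731 ± 29.2 FPKM in controls (1.21, adjusted p = 0.155, and 0.00982 without PM2.5 replicate 1). The zinc exporter SLC30A1 had a log2 fold change of -0.39 (adjusted p = 0.447).

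Targets of the aryl hydrocarbon receptor, the sensor of polycyclic aromatic hydrocarbons, were higher in 3 of 7 tested members and lower in 0 (3 and 0 adjusted over the list alone). The median was 0.51 and the camera adjusted p 0.00188 (adjusted p = 0.141 with an estimated correlation). CYP1A1, the receptor's classic target, went from 0.932 ± 0.0831 to 4.85 ± 1.24 FPKM (SD, n = 3; log2 fold change 1.58, SE 0.19, adjusted p = 0.00916). SERPINB2, a plasminogen activator inhibitor that also responds to inflammatory signals, went from 14.6 to 118 FPKM (2.96, adjusted p = 0.00248). TIPARP, a mono-ADP-ribosyltransferase, went from 6.83 to 17.03 FPKM (1.16, adjusted p = 0.0465). SLC7A5 did not pass the test (0.51, adjusted p = 0.435, and 0.00740 without PM2.5 replicate 1, where the median of the list was 0.93). CYP1B1 was listed at 0 in all 6 libraries. The ribosomal protein gene RPS10 (0 to 0.418 FPKM) and the splicing factor gene U2AF1 (0.124 to 0.828 FPKM), named after their values were seen, were near 0 too. A listed 0 therefore need not mean that a gene is silent.

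Endothelial identity genes fell in 12 of 20 tested members and rose in 1 (17 and 1 adjusted over the list alone). Their median was -1.42 and their camera adjusted p 7.27e-13 (adjusted p = 0.0454 with an estimated correlation). PECAM1, the junctional protein CD31, went from 167 ± 5.35 to 48.5 ± 7.01 FPKM (-1.77, SE 0.15, adjusted p = 0.00437). The adhesion molecule ICAM2 went from 82.8 to 24.0 FPKM (-1.75) and the guidance receptor ROBO4 from 37.3 to 9.16 FPKM (-1.93). The member that rose was the transcription factor SOX17 (1.28), named after its value was seen. VWF, below the filter, was not tested. The median of the list was -1.45, -1.28 and -1.46 in PM2.5 replicates 1, 2 and 3 taken singly. Adhesion molecules of endothelium fell in 5 of 14 members and rose in 0 (7 and 1 adjusted over the list alone). Camera gave adhesion molecules an adjusted p of 4.29e-04 (adjusted p = 0.141 with an estimated correlation). SELP, ICAM2, PECAM1, VE-cadherin (CDH5, -1.96) and ESAM (-0.79, named after its value was seen) fell. All of these but SELP also belong to the endothelial identity list, so the results of these lists are not independent. ICAM1, a leukocyte receptor induced by cytokines, read 15.6, 55.6 and 41.9 FPKM in PM2.5 replicates 1 to 3 against 12.02 ± 0.616 FPKM in controls. It missed the threshold (1.40, adjusted p = 0.133) and passed it without PM2.5 replicate 1 (1.92, adjusted p = 7.00e-04). SELE was below the filter and VCAM1 was listed at 0 in all 6 libraries, which need not mean that it is silent.

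Genes of vascular tone and nitric oxide moved both ways, with 2 of 13 higher and 3 lower (3 and 7 adjusted over the list alone). The camera direction was down, with an adjusted p of 0.0315 (adjusted p = 0.141 with an estimated correlation). EDN1, the caveolar protein CAV1 (-1.69) and the arginine-recycling enzyme ASS1 (-1.505) fell, while the cyclooxygenases PTGS2 (2.98) and PTGS1 (0.89, named after its value was seen) rose. The list missed the threshold without PM2.5 replicate 2 (adjusted p = 0.0802) and without PM2.5 replicate 3 (adjusted p = 0.0779). In this list 4 members were higher and 7 lower without PM2.5 replicate 1. Endothelial nitric oxide synthase, NOS3, stood at 117 ± 17.9 and 44.5 ± 17.7 FPKM (-1.46, adjusted p = 0.0658, and 0.00441 without PM2.5 replicate 1). Coagulation and fibrinolysis genes were higher in 4 of 17 and lower in 2 (6 and 5 adjusted over the list alone), with a camera adjusted p of 0.273. Their median (-0.16) had the opposite sign to the mean (0.27) and to the camera direction, up; without PM2.5 replicate 1, 8 coagulation genes were higher and 6 lower. Tissue factor (F3), which starts coagulation, went from 0.604 ± 0.142 to 3.88 ± 1.23 FPKM (1.58, adjusted p = 0.0184). The protease inhibitors TFPI2 (2.26) and SERPIND1 (1.04) also rose. The remaining members past the threshold, named after their values were seen, were tissue plasminogen activator (PLAT, 1.64), which rose, and urokinase (PLAU, -0.68) and the protein C receptor (PROCR, -0.79), which fell. Thrombomodulin (THBD) was not past the threshold (0.61, adjusted p = 0.197, and 0.00382 without PM2.5 replicate 1).

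Cell cycle and DNA replication genes fell in 16 of 31 members and rose in 0 (29 and 0 adjusted over the list alone). The median was -1.06, with a camera adjusted p of 5.21e-18 (adjusted p = 0.0708 with an estimated correlation). In PM2.5 replicates 1, 2 and 3 taken singly the median was -1.135, -1.139 and -0.814. TOP2A, the topoisomerase of dividing cells, went from 14.9 ± 0.441 to 2.58 ± 1.17 FPKM (-2.20, adjusted p = 0.00741). KIF20A (-2.13), MCM4 (-1.08), MCM7 (-1.05) and the proliferation marker MKI67 (-1.45, adjusted p = 0.0273) fell as well. Without PM2.5 replicate 1, all 31 tested members were lower. Replication-dependent histone genes were higher in 2 of 7 and lower in 0 (3 and 0 adjusted over the list alone). Camera gave histones an adjusted p of 0.00122 (adjusted p = 0.141 with an estimated correlation), and the list missed the threshold without PM2.5 replicate 1 (adjusted p = 0.0836, median 0.35 in place of 1.02). The members that rose, HIST1H2BD (1.20) and HIST1H2AC (1.02), are known to make polyadenylated transcripts outside S phase too. HIST1H2BK (0.76, adjusted p = 0.0530) and HIST1H2BJ (1.04, adjusted p = 0.356) did not pass the test. Targets of p53 were higher in 4 of 25 and lower in 0 (4 and 2 adjusted over the list alone; camera adjusted p = 0.757). The median (-0.15) and the mean (-0.01) of p53 targets were negative and the camera direction was up; 4 were higher and 4 lower without PM2.5 replicate 1. CDKN1A, the cell cycle inhibitor p21, went from 131 ± 2.84 to 241 ± 32.9 FPKM (0.87, adjusted p = 0.0322). The stress cytokine GDF15 went from 265 to 495 FPKM (0.89, adjusted p = 0.0308). The other members past the threshold were SESN2 (1.01) and PLK3 (0.66), named after their values were seen.

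Extracellular matrix and TGF-beta target genes fell in 10 of 28 members and rose in 3 (15 and 3 adjusted over the list alone). Their median was -0.71, and their camera adjusted p 1.11e-04 (adjusted p = 0.282 with an estimated correlation). Those that rose were the collagenase MMP1, the stromelysin MMP10 (1.81 ± 0.387 to 57.5 ± 9.50 FPKM) and the collagen cross-linking enzyme LOX (1.303). TIMP3, an inhibitor of metalloproteinases, went from 62.0 ± 4.17 to 12.4 ± 2.79 FPKM (-2.25, adjusted p = 0.00391). Among markers of other cell types, the epithelial list fell in 2 of 4 tested members and rose in 0 (3 and 0 adjusted over the list alone). Without PM2.5 replicate 1, 16 matrix genes were lower and 4 higher, and 4 epithelial markers were lower and 0 higher. Camera gave epithelial markers an adjusted p of 0.00163 (adjusted p = 0.150 with an estimated correlation). KRT7 (-1.82) and KRT8 (-1.298) fell, and KRT18 (-1.01, adjusted p = 0.140) and MUC1 (-0.40, adjusted p = 0.478) did not pass. Of the leukocyte list and of the list for fibroblasts and smooth muscle, 2 members each were above the filter, too few for a list test. LAPTM5 (-0.82, adjusted p = 0.0395) and RGS5 (-1.36, adjusted p = 0.0177) were lower. LYZ (-0.76, adjusted p = 0.201) and ACTA2 (-0.05, adjusted p = 0.886) did not pass. Adjusted over the list alone, 2 leukocyte markers and 1 fibroblast or smooth muscle marker were lower and 0 higher.

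Autophagy and lysosome genes were higher in 2 of 24 and lower in 0 (3 and 0 adjusted over the list alone). Their median was 0.28 and their camera adjusted p 0.00164 (adjusted p = 0.0766 with an estimated correlation). The autophagosome protein MAP1LC3B (1.03) and cathepsin L (CTSL, 1.15) rose, with GLA at 0.80 (adjusted p = 0.0594) and NEU1 at 0.58 (adjusted p = 0.0999). In total 9 members were higher without PM2.5 replicate 1. HIF targets were higher in 2 of 16 and lower in 0 (4 and 0 adjusted over the list alone). With a median of 0.13, their camera adjusted p was 0.0260 (adjusted p = 0.141 with an estimated correlation) and 0.0909 without PM2.5 replicate 2. LOX and the circadian repressor BHLHE40 (0.83) rose, while VEGFA (0.73, adjusted p = 0.0603) and NDRG1 (0.87, adjusted p = 0.0820) missed the threshold; 5 HIF targets were higher and 2 lower without PM2.5 replicate 1. Glycolysis genes were lower in 2 of 17 and higher in 0 (6 and 1 adjusted over the list alone). With a median of -0.33, camera gave them an adjusted p of 0.00503 (adjusted p = 0.411 with an estimated correlation) and 0.157 without PM2.5 replicate 1, where the median was -0.17, with 8 members lower and 3 higher. Lactate dehydrogenase A (LDHA, -1.33) and the lactate exporter SLC16A3 (-1.07) fell, and PFKL (-0.77, adjusted p = 0.0604) and PKM (-0.73, adjusted p = 0.0736) did not pass.

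Ribosomal protein genes were called higher as a list by camera (adjusted p = 4.05e-04, median 0.44) with 0 of 34 members past the threshold, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 the limma test also gave 0 members. The call was lost with an estimated correlation, which was 0.979 (adjusted p = 0.565), and without PM2.5 replicate 1 (adjusted p = 0.373, median 0.05). Without PM2.5 replicates 1 and 2, where the treated group is 1 library, the median of these genes was 0.28. Their medians were 1.24, -0.16 and 0.28 in PM2.5 replicates 1, 2 and 3. RPL15 (0.44), RPL6 (0.57), RPL19 (0.51) and RPL5 (0.45) had adjusted p-values of 0.327 to 0.368. Nuclear genes of oxidative phosphorylation, with medians of 1.02, -0.27 and 0.05 in the same libraries, had 0 of 31 members past the threshold, also adjusted over the list alone. Camera gave them an adjusted p of 0.180, and 3 members had an unadjusted limma p under 0.05. SDHA (-0.57) and ATP5F1B (-0.42) had the smallest p-values. Of the 13 mitochondrially encoded protein genes, 0 passed (0 adjusted over the list alone, and 0 at an unadjusted p under 0.05; camera adjusted p = 0.237, 0.0417, down, without PM2.5 replicate 1, and 9.99e-06, down, without PM2.5 replicates 1 and 2), with MT-CYB at -0.33 and MT-ND1 at -0.32.

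Lists for cholesterol (24 tested members) and fatty acid metabolism (15 tested members) had 0 members past the threshold, also adjusted over the list alone, with 6 and 2 at an unadjusted limma p under 0.05 and camera adjusted p-values of 0.654 and 0.268. In these lists, and in those of metallothioneins, oxidative phosphorylation, mitochondrially encoded and ribosomal proteins, limma-voom on recovered reads also called 0 members. The cholesterol list had a positive median (0.02), a negative mean (-0.09) and the camera direction down. DHCR7 (-0.59), FADS2 (-0.56) and the fatty acid synthase FASN (-0.85) did not pass, with adjusted p-values from 0.158 to 0.185. Interferon-stimulated genes had 2 of 23 lower and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 0.268): OASL fell by 0.71 and OAS2 by 0.93 on the log2 scale. Of these genes 9 were lower and 3 higher without PM2.5 replicate 1, and without PM2.5 replicates 1 and 2 the list passed downward (adjusted p = 0.00144) with 8 lower.

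**Figure D3:**
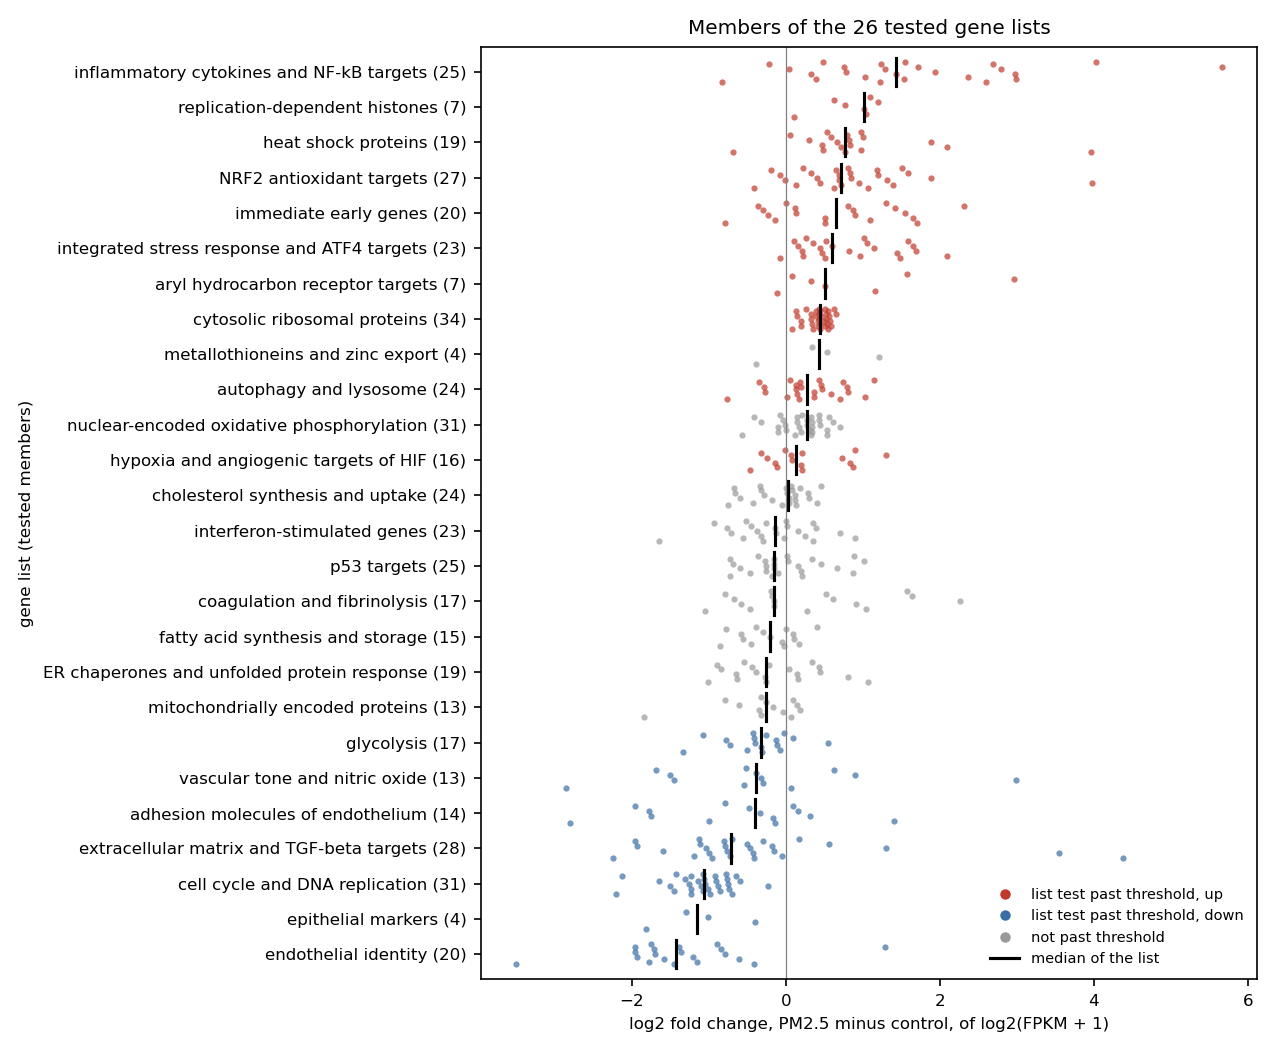
Log2 fold change (PM2.5 minus control, of log2(FPKM + 1)) of each tested member of the 26 tested gene lists, with 1 point per gene and a black line at the median of the list; numbers in brackets are tested members. Red and blue lists passed the camera test upward and downward at the preset correlation and grey lists did not; medians run from -1.42 for endothelial identity to 1.43 for inflammatory cytokines.

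Some of the named genes share sequence or position with others, and no source used here says whether counting used strand. HSPA1A and HSPA1B, CCL3, TRIM16L, FTH1, the histones and the ribosomal protein genes have near-identical copies or pseudogenes, so their split of reads is uncertain. Of the 75 called genes that the fixed rule names, 31 share exon bases with another GENCODE gene and are uncertain to that extent: ATP6V0D2, BHLHE40, CCL3, CDKN1A, CEBPB, COL9A3, DDIT3, DNAJB1, DNAJB9, FTH1, HHIP, HSPA1B, ICAM2, IL6, KIF20A, KRT7, KRT8, LIF, LOX, MAP1LC3B, MCM7, MMP1, MMRN2, RGS5, ROBO4, SERPINB2, SLC16A3, STAB1, TFPI2, TIPARP and TRIM16L. Of 20 called genes named after their values were seen, COL17A1, ITGA6, PLAU, PLK3 and PROCR do so as well.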

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

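The 580 genes past the threshold all have groups that do not overlap, which leaves little room for a change of sign, so their unchanged direction under the alternatives that tested them says little about stability. Of the 33 named genes not past it, 2 changed sign under an alternative: ACTA2 (-0.05 to 0.0957 without PM2.5 replicate 1) and HIST1H2BJ (1.04 to -0.00668 without PM2.5 replicates 1 and 2). Counts moved more: without a filter on low values 118 genes were higher and 171 lower among the 26201 then tested. In the main fit, with a log2 fold change of at least 1 required as well, 161 genes were higher and 187 lower. Leaving out each replicate in turn gave 17 to 1078 genes higher, 8 to 1390 lower and 15 to 17 lists, the highest gene counts without PM2.5 replicate 1. Without PM2.5 replicates 1 and 2 together, chosen after seeing the data and assuming that the lone PM2.5 library varies like the controls, 914 genes were higher, 1083 lower and 572 of the 580 stayed past the threshold; the cause was not tested. Of the 75 named genes past the threshold, 30, 17 and 20 stayed past it without control replicate 1, 2 and 3, and 75, 56 and 59 without PM2.5 replicate 1, 2 and 3; 18 of the 33 other named genes passed without PM2.5 replicate 1. The replicate numbers are shared by both groups, and nothing in the labels says what they mark. The deviations of same-numbered libraries correlated at 0.264, 0.115 and 0.031 across genes. The deviations within a group are not independent of each other, so these values cannot show whether same-numbered libraries are paired. With a replicate block, 124 genes were higher and 151 lower, with 18 lists, and not every library correlated best with its own number (control 2 with PM2.5 replicate 3 at 0.232, for example). Median-of-ratios scaling moved nothing, being the authors' own. Library totals (238 and 269), limma-voom (226 and 319), a stricter filter (291 and 426), protein-coding nuclear genes (276 and 405) and a pseudocount of 0.1 (264 and 294) stayed within 1.5 times the main counts. With an estimated correlation 4 of the 17 lists passed. The fry test, which asks whether the genes of a list move one way and does not compare them with other genes, passed 16 lists, 14 of them among the 17. It missed the lists of glycolysis (adjusted p = 0.0537), extracellular matrix (0.0818) and ribosomal proteins (0.372), and added ER chaperones, downward (0.0409), and coagulation, upward (0.0373). Without PM2.5 replicates 1 and 2 together, the interferon (adjusted p = 0.00144) and mitochondrially encoded lists (9.99e-06) passed downward, and those of HIF targets (0.0574), glycolysis (0.3315) and histones (0.05105) missed the threshold. The list of nuclear oxidative phosphorylation genes passed upward without a filter (adjusted p = 0.0255), with the block (0.0490) and without PM2.5 replicate 2 (0.00400). The epithelial list missed the threshold without a filter (0.0672), and the vascular tone list with the stricter filter (0.0640) or protein-coding genes only (0.0551). The planned DESeq2 and edgeR fits were not run, because the plan set the limma test for deposited values that are not counts. The recovered reads were fitted with limma-voom only. Depth limits genes with few reads. In PM2.5 replicates 1 and 2 some genes are at 0 that the other libraries count, more than depth accounts for.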

Other observations

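The genes singled out in this paragraph were chosen after their values were seen, and the explanations weighed later in this part were tested after the data were seen; the ribosomal protein and endothelial identity lists and the comparison of splits were fixed before. TFRC, the transferrin receptor that takes up iron, went from 19.0 to 3.93 FPKM (log2 fold change -2.02), while FTH1, which stores iron, went from 463 to 1063 FPKM (1.19), and the 6 other tested genes of iron uptake and storage did not pass. Among 12 tested genes of hemidesmosomes and keratins 6 fell, the others not passing: KRT7 and KRT8 of the epithelial list, the integrins ITGB4 (-2.19) and ITGA6 (-1.09), the collagen COL17A1 (-1.89) and the keratin KRT80 (-2.02). The BMP and Notch targets ID1 (-3.04) and HES1 (-2.16) and the Notch modifier LFNG (-2.48) fell, while the 9 other tested genes of these pathways did not pass. Of 4 tested EGF-family ligands AREG rose (1.83) and 3 did not pass. These counts moved without PM2.5 replicate 1, to 2 higher and 2 lower of the 8 iron genes, 9 lower of the hemidesmosome and keratin genes, 7 lower of the 12 BMP and Notch genes and 2 higher of the EGF-family ligands. Among noncoding genes, LUCAT1, a long noncoding RNA, went from 0.442 to 3.86 FPKM (1.75, limma adjusted p = 0.00511). The microRNA gene MIR126 went from 6.78 ± 3.32 to 0.258 ± 0.446 FPKM (SD, n = 3, log2 fold change -2.57, adjusted p = 0.0250). It lies within its host gene EGFL7, which also fell (-1.96), so its 150 bp reads may come from the EGFL7 transcript. The level of the mature microRNA was not measured. The fall of MIR126 is uncertain at this low level, since PM2.5 replicates 1 and 2 miss many genes that have few reads elsewhere.

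PM2.5 replicates 1 and 2 had 182 and 276 genes with exactly 1 read, where the other 4 libraries had 1899 to 2269. Fewer reads were not the reason, since replicate 1 held 1.02 times and replicate 2 1.19 times the reads of PM2.5 replicate 3, and a minimum count set in processing would have left no gene at 1 read. Of 1883 genes whose lowest level among the other 4 libraries was 5 to 20 reads at a depth of 15000000 reads, 52.2% were at 0 in replicate 1 and 11.8% in replicate 2, where Poisson counting allows 0.12% and 0.016%. Genes with 4 to 30 reads outnumbered those with 1 to 3 reads by 4.56 and 5.53 times there, against 0.954 to 1.04 in the other libraries. Few starting molecules copied many times may be the source of this pattern; whether treated cells yielded less RNA was not tested.

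The list of ribosomal protein genes passed camera at the preset correlation only (adjusted p = 0.565 with an estimated correlation), with medians of 1.24, -0.16 and 0.28 in PM2.5 replicates 1, 2 and 3. Replicate 1 had the strongest relation to gene length of the 6 libraries (Spearman's correlation across genes -0.406, against -0.207 to 0.136 in controls). There, 161 genes of like transcript length and level had a median of 0.323, which was 0.912 below that of the ribosomal protein genes. A preference for short transcripts may account for part of the rise and is not excluded. In PM2.5 replicates 2 and 3 the median of the ribosomal protein genes lay 0.15 and 0.389 above that of the matched genes. Replicate 1 as the sole source cannot be told apart from a change in PM2.5 cells. Without it the median was 0.05 in place of 0.44 and the list missed the threshold (camera adjusted p = 0.373). Without PM2.5 replicates 1 and 2 the median was 0.28, from a single treated library. The estimated correlation between the members was 0.979, so they move nearly as 1 gene. A camera p at the preset correlation therefore carries little weight for this list. Over the scalings, filters, fits and left-out libraries that keep PM2.5 replicate 1, the adjusted p at the preset correlation ran from 8.14e-09 to 8.00e-04. The treatment stays open as an explanation, untested.

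Endothelial identity genes fell with a median of -1.42. The low complexity of PM2.5 replicates 1 and 2 would have lowered other genes of like transcript length and level as well, but the median of the list minus that of 187 such genes was -1.071 and -1.163 in these libraries (log2). Nor did markers of 3 other cell types rise as cells mixed in at such a share would require: 0 members of the epithelial, leukocyte and fibroblast lists were called higher, and the largest gain of any of them was 0.416 FPKM, in NAPSA. Of those markers, 8 are above the filter in these cells, and cell types outside the 3 lists were not examined. A response of the cells to PM2.5 stays open as a hypothesis.

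The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 580 genes past the threshold and was the only 1 of the 10 to give as many, and the highest of the other splits gave 0. Every other split puts control and PM2.5 libraries in both groups, so any difference between control and PM2.5 adds to the spread there. Few calls in those splits were therefore to be expected, and the comparison cannot tell the treatment from another difference between the groups.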
